A study of Homo sapiens with 12 samples.

How the data were processed

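Total RNA of 12 K562 cultures was labelled with Cy3 and hybridized to Agilent one-colour arrays, in 4 groups of 3: control, wild-type CXCR4, N119A CXCR4 and N119S CXCR4. Group and replicate came from the labels, which call the 3 arrays of a group biological replicates, and all 12 arrays were used. Per the file headers the scanner intensity was extracted with Agilent Feature Extraction 10.5.1.1, which subtracted background and removed spatial trends, and no normalization between arrays was applied. The deposited series table holds log2 ratios whose scaling between arrays is not stated. Its control and wild-type columns were centred on the median of the control arrays (r = 1), and its N119A and N119S columns on the median of the wild-type arrays (r = 1, against 0.813 to 0.847 for the control median). The deposited log2 ratios therefore have 2 baselines and were used only as alternatives to the scanner intensity.

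The 51538 spots that are not controls gave 50238 probes. Outlier spots were left out, spots of a probe were averaged on the log2 scale, and each array was shifted by its 75th percentile. A probe was kept if it was well above background on at least 3 of 12 arrays, which left 33639 probes, and the brightest probe stood for each of 22429 gene or transcript names. Names came from RefSeq by accession for 28595 probes and by symbol or synonym for 4174, and the file's own name was kept for 17469; 15429 of the tested names matched RefSeq. The array design was built on an older genome assembly than the annotation, so no coordinates are given.

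Groups were fitted together for all 12 arrays with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8) for reading. Moderated t-tests (prior degrees of freedom 2.65) were made for 7 comparisons, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 7 comparisons were each CXCR4 group against control, each mutant against wild-type CXCR4, N119S against N119A, and the mean of both mutants against wild-type CXCR4. A set of 28 gene lists was tested with camera (preset correlation 0.01) on 22193 genes with complete values, with p adjusted over the lists of a comparison, and members were also adjusted over their list alone. The p-values measure the spread between these samples, and 3 arrays a group limit the precision of every value.

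Groups, comparisons, lists, the rule for naming genes and most alternatives were chosen before the data were examined. The rule named CXCR4, then up to 10 genes per direction and comparison with the largest differences among those past the threshold with non-overlapping replicates, then up to 4 passing members of each list and genes shared by both mutants; the text prints a part of these, and some of the results are not reported here. Where no array of the dimmer group was well above background, a bound on the fold difference, or no size, is printed in place of the estimate. Where some but not all of its arrays were, the estimate is printed, though it rests partly on signal near background. MS4A4A in control, SPARC with N119A and OCIAD2 with N119S were such cases.

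The alternatives were normexp background correction (offset 50), quantile normalization, a percentile over probes detected on all arrays, other filters, other ways to join probes, trended and robust moderation, array weights, separate fits of the groups compared, slide as a fixed term, as a random block or as a single-slide subset, the side of the slide (1 of 2) as a term, a replicate block, the series table, and leaving out each array. For lists, camera with an estimated correlation and fry were added. Leaving out control replicate 1 and wild-type CXCR4 replicate 2, and moving the mutant columns of the series table to the control baseline, were chosen after seeing the data. Control and wild-type arrays and N119A replicates 1 and 2 lay on slide 1, and N119A replicate 3 with all N119S arrays on slide 2, so a slide term is estimated through N119A alone. The control arrays serve 3 comparisons and were too few to split, so shared calls are set beside 20 simulations of groups without effect. In these all arrays, control included, were drawn gene by gene around the gene's overall mean with each group's spread.

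The tests were tried on simulated data with 200 changed genes out of 22429. With 1 spread per gene, N119A against control recovered 4 of 67 genes at 1 log2, 35 of 67 at 2 and 56 of 66 at 4, and called 7 of 22229 unchanged genes. For N119A against wild-type CXCR4 the counts were 5, 41 and 58, with 5 unchanged genes called. With a separate spread in each group, 16, 43 and 57 were recovered and 52 unchanged genes called against control, and 18, 44 and 59 with 155 called against wild-type CXCR4. Groups of unequal spread thus gave more false calls in the pooled fit.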

Results

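Gene expression was measured in K562 cells, a human leukaemia line with erythroid and megakaryocytic features, on one-colour arrays. The 4 groups of 3 arrays were control cells and cells transfected with wild-type, N119A or N119S CXCR4. CXCR4 is the receptor for the chemokine CXCL12, and the labels call both substitutions constitutively active. Per the labels the transfected cells were induced and growing exponentially, the control cells were untreated, and the 3 arrays of a group were biological replicates. The 75th-percentile signal was 257.5, 412.4 and 388.8 on the control arrays, 383, 96.8 and 468.1 with wild-type CXCR4, 346, 309.1 and 359 with N119A and 297.4, 300.1 and 260.9 with N119S. Between 50.5% and 62.8% of probes were well above background on an array. All log2 values below were differences between group means (± SE, n = 3 per group) over 22429 gene or transcript names, and adjusted p-values came from limma with the Benjamini-Hochberg correction.

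**Figure D1:**
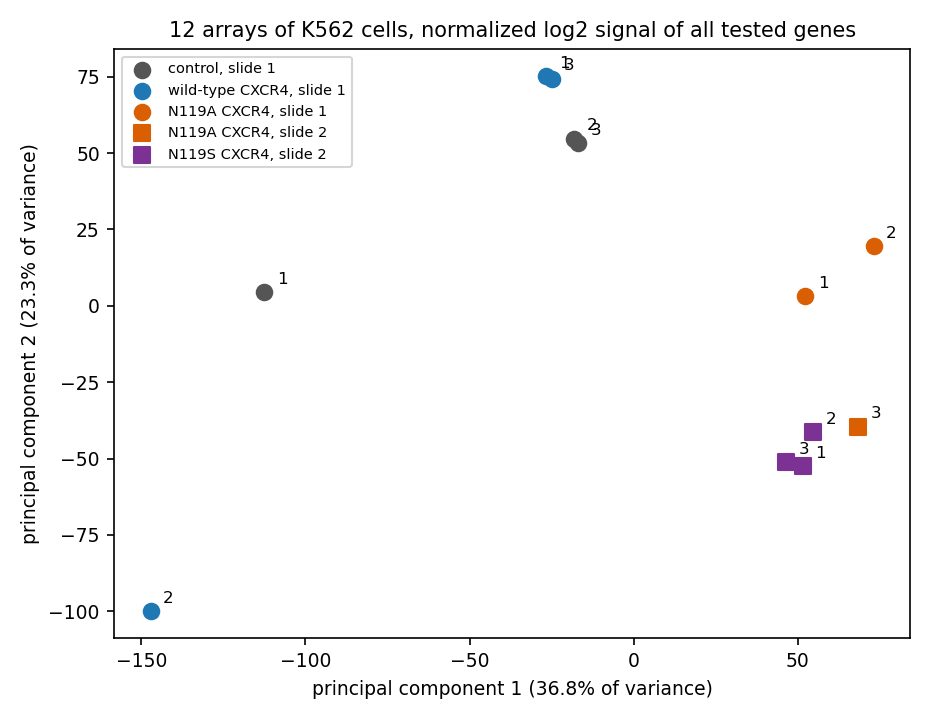
First 2 principal components of the 12 arrays. Control replicate 1 and wild-type CXCR4 replicate 2 lay far from the other arrays of their groups.

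Control replicate 1 and wild-type CXCR4 replicate 2 stood apart from their groups, with positions of -112.6 and -147.2 on the first component, which held 36.8% of the variance. Relative to the other arrays of their groups, erythroid genes were lower on both (median log2 -1.71 and -1.33), as were DNA replication genes (-1.36 and -1.91), mitosis genes (-1.2 and -1.17) and cholesterol synthesis genes (-1.22 and -1.34). Interferon-stimulated genes were higher on these arrays (1.41 and 1.6), as were NF-kB targets (2.11 and 1.18), stress genes of the ATF4 kind (1.05 and 1.11) and hypoxia genes (0.71 and 0.89). All 12 arrays stayed in the tests, and for a part of the results the values without these arrays are given too. Control cells were untreated, so every difference against control includes transfection and induction.

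CXCR4 itself was read by a single probe, in the 3′ untranslated part of the transcript, which a coding-only transgene would lack; whether the constructs hold this part was not given in the sources used here. Its signal was 691.1, 40.5 and 37.8 in control, 23.9, 376 and 30.1 with wild-type CXCR4, 3.6, 3.5 and 3.9 with N119A and 3.4, 3.3 and 13.2 with N119S. The probe was well above background on all 6 control and wild-type arrays and on none of the mutant arrays. CXCR4 did not pass for N119A (adjusted p = 0.11) or N119S (adjusted p = 0.152) against control. Without control replicate 1 and wild-type CXCR4 replicate 2, CXCR4 passed as lower for N119A (adjusted p = 0.0061) and for N119S (adjusted p = 0.0196) against control. Against wild-type CXCR4 on those 10 arrays it passed as lower for N119A (adjusted p = 0.0145) and for N119S (adjusted p = 0.047), and no size is given because the mutant arrays were not well above background.

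Wild-type CXCR4 cells were compared with control cells to ask what the unmutated receptor and its transfection changed. KANK1, a regulator of actin at adhesion sites, rose by 5.11 ± 0.53 (adjusted p = 0.00229). CA2, a carbonic anhydrase of red cells, rose by 3.98 ± 0.35 (adjusted p = 0.00109). MS4A3, a membrane protein of granulocyte progenitors, rose by 3.89 ± 0.42 (adjusted p = 0.00277), and the neural gene FAM171B was at least 7.87-fold higher (adjusted p = 0.00174), not well above background in control. OCIAD2, an endosomal and mitochondrial membrane protein, fell by 7.31 ± 0.30 (adjusted p = 2.19e-06). The small heat shock protein HSPB2 (-4.84 ± 0.26, adjusted p = 1.87e-05) and the semaphorin receptor PLXNA2 (-3.23 ± 0.28, adjusted p = 0.00109) fell as well. FPR3, a formyl peptide receptor of monocytes, was at least 4.08-fold lower (adjusted p = 0.00257) and LEFTY2, an antagonist of Nodal, at least 3.7-fold lower (adjusted p = 0.00806), both not well above background with wild-type CXCR4. Each fold bound set the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

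In all, 96 genes rose and 44 fell with wild-type CXCR4 against control. Among 41 erythroid genes, CA2 alone rose and none fell, in the count over the list alone too, while the list as a whole ranked lower (median -0.38, adjusted p = 0.0345 by camera; adjusted p = 0.987 with an estimated correlation, and 0.0651 with slide as a term). On the 10 arrays left without those that stood apart 2 erythroid genes rose and 13 fell (adjusted p = 9.35e-07; adjusted p = 0.358 with an estimated correlation). Of 31 early response and ERK target genes 9 rose there (adjusted p = 3.94e-07; adjusted p = 0.0912 with an estimated correlation) and none over all arrays. Of 27 oxidative stress genes none passed over all genes and 2 fell when adjusted over the list alone (median -0.14, adjusted p = 0.0101; adjusted p = 0.11 with an estimated correlation). The matrix glycoprotein gene SPARC rose by 2.44 ± 0.45 (adjusted p = 0.0478), and the chaperone gene CRYAB fell by 2.58 ± 0.33 (adjusted p = 0.00868). BCL2L11, which promotes apoptosis, fell by 1.53 ± 0.28 (adjusted p = 0.0478). None of 25 CXCR4 signalling components passed (median -0.13). Without the arrays that stood apart 1068 genes passed, 138 of them among the 140. When only these 2 groups were fitted 2 genes passed, both lower, and 17 did with the side of the slide (1 of 2) as a term.

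N119A cells were compared with control cells to ask what a constitutively active receptor changed. EYA2, a transcriptional co-activator with phosphatase activity, was at least 199-fold higher (adjusted p = 7.24e-07) and not well above background in control. MS4A4A, a membrane protein of macrophages, rose by 8.41 ± 0.37 (adjusted p = 6.84e-07), and MS4A3 by 8.36 ± 0.42 (adjusted p = 1.53e-06). On control replicates 1 and 3 MS4A4A (-4.55 and -4.81) lay below the lowest value of a probe well above background (-4.46 and -4.65). RUNX1T1, a corepressor fused to RUNX1 in myeloid leukaemia, rose by 6.44 ± 0.41 (adjusted p = 6.27e-06), and MLLT3, which maintains blood stem cells, by 6.53 ± 0.66 (adjusted p = 0.000159). CYB5A, which encodes a cytochrome of the endoplasmic reticulum, fell by 8.96 ± 0.78 (adjusted p = 5.42e-05), and FHL2, a cofactor of transcription, fell by 6.39 ± 0.32 (adjusted p = 1.43e-06). MARCKS, a membrane substrate of protein kinase C, was at least 30.5-fold lower (adjusted p = 2.22e-06), and MECOM, a stem-cell transcription factor, at least 24.3-fold lower (adjusted p = 0.000328), both not well above background with N119A.

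Overall 705 genes rose and 1128 fell with N119A against control. The excess of lower genes shrank when the arrays that stood apart were left out (2517 higher and 2698 lower) and turned with array weights (3400 and 3016). Of 28 cholesterol synthesis genes 11 fell and none rose, with 16 lower when adjusted over the list alone (median -1.28, adjusted p = 1.75e-10 by camera; adjusted p = 0.844 with an estimated correlation). STARD4, which carries cholesterol within cells, was at least 20.1-fold lower (adjusted p = 2.58e-07). INSIG1, which holds sterol sensors in the endoplasmic reticulum, fell by 2.61 ± 0.38 (adjusted p = 0.00156), and the synthesis enzyme MSMO1 fell by 3.80 ± 0.61 (adjusted p = 0.00292). As many as 26 of the cholesterol genes fell without the arrays that stood apart. Of 33 hypoxia and glycolysis genes 6 fell and none rose, 7 over the list alone (median -0.61, adjusted p = 3.39e-05; adjusted p = 0.844 with an estimated correlation). Among these, CA9, a carbonic anhydrase of hypoxic cells, was at least 67.5-fold lower (adjusted p = 3.6e-05), and the oxygen sensor EGLN1 fell by 3.70 ± 0.27 (adjusted p = 1.78e-05). Without the same arrays the hypoxia median was -0.38, with 13 genes lower and 1 higher.

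Among 32 interferon-stimulated genes, 4 fell and none rose with N119A against control, 10 over the list alone (median -0.86, adjusted p = 0.000102; adjusted p = 0.844 with an estimated correlation). The RNA sensor IFIH1 fell by 5.23 ± 0.67 (adjusted p = 0.000702) and USP18, which restrains interferon signalling, fell by 5.10 ± 0.97 (adjusted p = 0.00805). The interferon median was -0.61 without the arrays that stood apart, with 11 lower and 2 higher. The chemokine gene CCL2 (-4.17 ± 0.57, adjusted p = 0.00101) and NFKB1 (-2.33 ± 0.37, adjusted p = 0.00295) were the 2 of 21 NF-kB targets that fell, also over the list alone, and none rose. The NF-kB list ranked lower (median -0.63, adjusted p = 0.00769; adjusted p = 0.844 with an estimated correlation, and 0.3 without those arrays). In the fibroblast and epithelial list 4 of 16 genes fell, 5 over the list alone, among them SPARC (-6.18 ± 0.45, adjusted p = 1.78e-05). That list had a median of -0.05 but a mean of -1.04 (adjusted p = 0.04; adjusted p = 0.844 with an estimated correlation, and 0.3 without those arrays). Of 15 lymphocyte genes 3 fell, also over the list alone, among them CD3D (-3.73 ± 0.50, adjusted p = 0.000881). Lymphocyte genes had a median of -0.05 and a mean of -0.67 (adjusted p = 0.047; adjusted p = 0.844 with an estimated correlation, and 0.127 without those arrays).

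Of 15 stem and progenitor genes with N119A against control 1 rose and 3 fell, also over the list alone, and the list did not pass (median -0.08, adjusted p = 0.327). The growth factor receptor KIT (-5.70 ± 0.60, adjusted p = 0.000204) and the transporter ABCG2 (-2.97 ± 0.42, adjusted p = 0.00129) were among the lower. Of 41 erythroid genes 1 rose and 2 fell, and the list did not pass (median 0.18, adjusted p = 0.434). CA1 rose by 5.30 ± 0.52 (adjusted p = 0.000129), and AHSP, a chaperone of alpha globin, fell by 3.34 ± 0.66 (adjusted p = 0.00981). The proteoglycan SDC1 fell by 3.70 ± 0.40 (adjusted p = 0.000231). Of 24 migration and adhesion genes 3 fell and 1 rose, 5 and 1 over the list alone (median -0.32, adjusted p = 0.0431; adjusted p = 0.844 with an estimated correlation, and 0.3 without the arrays that stood apart). The mitotic genes TOP2A (1.37 ± 0.30, adjusted p = 0.0165) and CDC20 (1.57 ± 0.37, adjusted p = 0.0249) rose, and the other 32 of that list did not pass, also over the list alone. Mitosis genes ranked higher (median 0.55, adjusted p = 0.0064; adjusted p = 0.925 with an estimated correlation). None of 36 DNA replication genes passed (median 0.58, adjusted p = 0.0331; adjusted p = 0.925 with an estimated correlation). Without the arrays that stood apart the medians of these cell cycle lists were 0.12 (adjusted p = 0.313) and 0.01 (adjusted p = 0.729). Of 26 histone genes none passed (median 0.4, adjusted p = 0.0431; adjusted p = 0.844 with an estimated correlation). Of 40 respiratory chain subunits ATP5PD alone rose, none over the list alone (median 0.35, adjusted p = 0.0451; adjusted p = 0.925 with an estimated correlation, and 0.963 without those arrays).

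Downstream of the receptor, RGS18, which shortens G-protein signals in blood cells, was at least 7.19-fold higher with N119A than in control (adjusted p = 0.00267), and RGS3 fell by 2.55 ± 0.67 (adjusted p = 0.0417). These were the only 2 of 25 CXCR4 signalling components to pass. SPRY1, an inhibitor of growth factor signalling, was at least 4.71-fold higher (adjusted p = 0.000838). SPRY4 (-1.33) fell, as did EGR2, which was not well above background with N119A, out of 31 early response and ERK target genes. BCL2L11 rose by 1.15 ± 0.28 (adjusted p = 0.0313). The 2 N119A arrays that shared a slide with all control arrays gave 588 genes in place of 1833.

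N119S cells were compared with control cells to ask the same question of the second substitution. EYA2 was at least 179-fold higher (adjusted p = 1.39e-06) and ZIC1, a zinc-finger factor of neural development, at least 26.8-fold higher (adjusted p = 8.02e-06). The glycosyltransferase MGAT4A was at least 25.1-fold higher (adjusted p = 4.45e-06), and all 3 were not well above background in control. MS4A4A rose by 7.96 ± 0.37 (adjusted p = 1.39e-06) and MS4A3 by 6.69 ± 0.42 (adjusted p = 9.46e-06). OCIAD2 fell by 7.20 ± 0.30 (adjusted p = 5.17e-07). HSPB2 was at least 35.9-fold lower (adjusted p = 2.02e-07) and CYB5A at least 315-fold lower (adjusted p = 4.24e-05). RASGRP1, an activator of Ras, was at least 21.7-fold lower (adjusted p = 5.51e-06), and these 3 genes were not well above background with N119S. Neurotensin (NTS, 8.86 ± 0.99, adjusted p = 0.000487) and S100P (-6.71 ± 0.80, adjusted p = 0.000698) also passed, yet with slide as a term their adjusted p-values were 0.105 and 0.167.

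With N119S against control 1104 genes rose and 1016 fell. More fell than rose under each other scaling, 540 higher and 587 lower with normexp background, 883 and 1173 with quantile normalization, and 909 and 952 with the percentile of detected probes. Of 33 hypoxia and glycolysis genes 14 fell and none rose, 19 over the list alone (median -1.39, adjusted p = 3.58e-16; adjusted p = 0.501 with an estimated correlation). CA9 was at least 64.3-fold lower (adjusted p = 3.73e-05), EGLN1 fell by 2.68 ± 0.27 (adjusted p = 0.000227) and the glycolytic aldolase ALDOC fell by 2.21 ± 0.30 (adjusted p = 0.0014). The hypoxia genes that fell numbered 28 without the arrays that stood apart (median -0.96). Of 28 cholesterol genes 10 fell and 1 rose, 13 and 1 over the list alone (median -1.12, adjusted p = 3.86e-08; adjusted p = 0.855 with an estimated correlation). STARD4 fell by 2.98 ± 0.24 (adjusted p = 4.2e-05) and MSMO1 was at least 13.8-fold lower (adjusted p = 0.00271). Of 32 interferon-stimulated genes 6 fell and none rose, 7 over the list alone (median -0.75, adjusted p = 8.76e-05; adjusted p = 0.98 with an estimated correlation). IFIH1 was at least 24.7-fold lower (adjusted p = 0.00216) and IFITM1, a viral entry inhibitor, fell by 1.33 ± 0.22 (adjusted p = 0.00548), and without the same arrays the interferon median was -0.35.

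RGS18 was at least 26.2-fold higher with N119S than in control (adjusted p = 0.000294), 1 of 3 signalling components to pass out of 25, and SPRY1 was at least 7.37-fold higher (adjusted p = 0.000416). CA2 rose by 1.91 ± 0.35 (adjusted p = 0.00872), and of 41 erythroid genes 1 rose and 1 fell. With the arrays that stood apart left out 4 erythroid genes rose and 24 fell (median -0.75, adjusted p = 1.09e-07; adjusted p = 0.294 with an estimated correlation). On those 10 arrays 12 of 36 DNA replication genes fell (median -0.39, adjusted p = 0.000134; adjusted p = 0.746 with an estimated correlation). Of 40 ribosomal protein genes 20 rose there (median 0.47, adjusted p = 2.99e-05; adjusted p = 0.795 with an estimated correlation) and none over all arrays. ABCG2 rose by 1.67 ± 0.42 (adjusted p = 0.033), against its fall with N119A, and of 15 stem and progenitor genes 3 rose and 1 fell. ME1, an NADPH-producing enzyme, fell by 2.38 ± 0.19 (adjusted p = 4.2e-05). No N119S array shared a slide with a control array, and 111 of the 2120 genes kept their calls with slide as a term, STARD4, ME1 and CA9 among them.

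**Figure D2:**
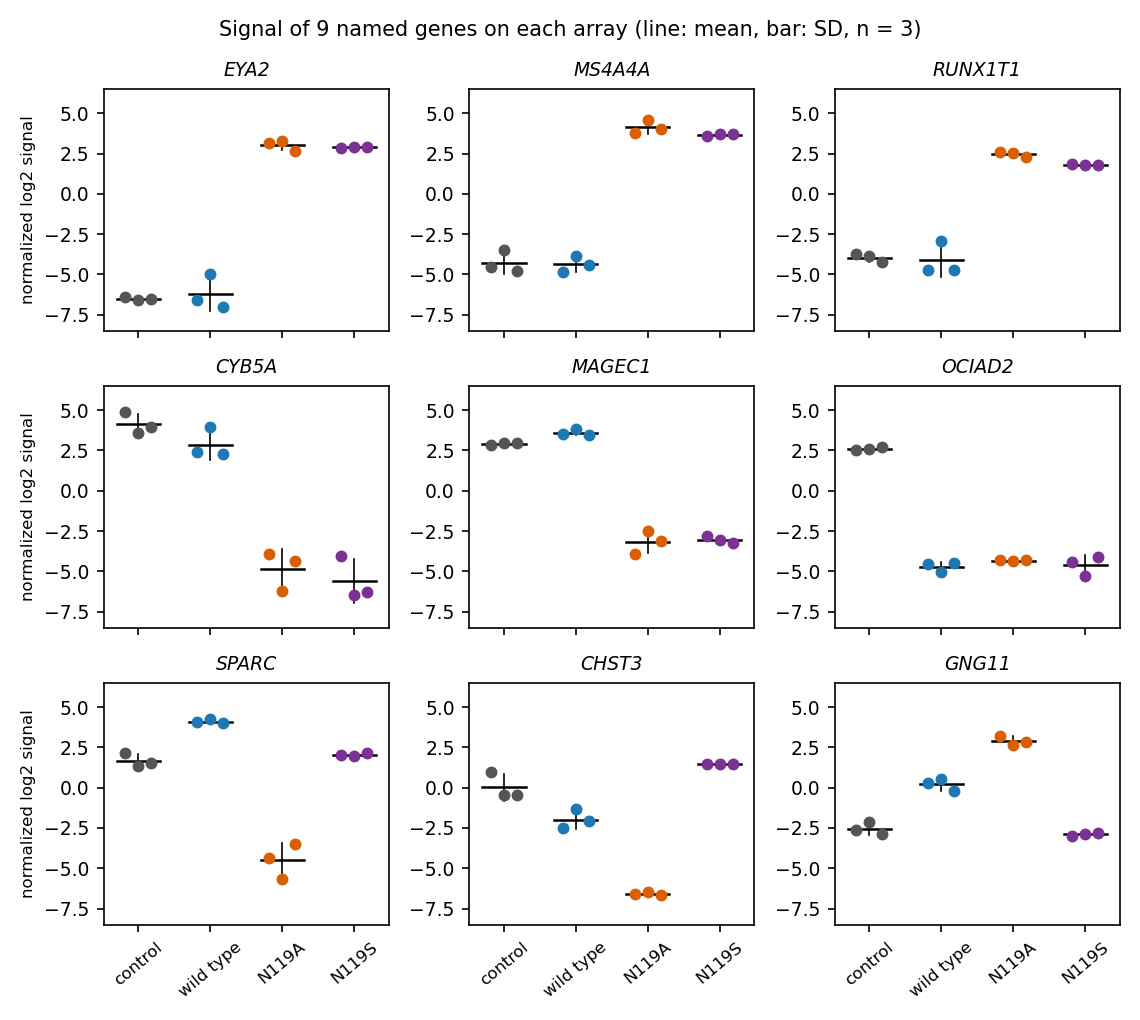
Normalized log2 values of named genes on each of the 12 arrays. Genes shared by both mutants and genes that differ between them are grouped.

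N119A and N119S were each compared with wild-type CXCR4 to ask what the substitutions added to the receptor. With N119A, MS4A4A rose by 8.48 ± 0.37 (adjusted p = 6.3e-07), and NXF3, an RNA export factor of the germ line, by 7.39 ± 0.71 (adjusted p = 8.29e-05). RUNX1T1 rose by 6.61 ± 0.41 (adjusted p = 5.95e-06) and PAGE1, a cancer-testis antigen, by 5.76 ± 0.52 (adjusted p = 5.84e-05). EYA2 was at least 140-fold higher, not well above background with wild-type CXCR4 (adjusted p = 7.81e-07). SPARC fell by 8.62 ± 0.45 (adjusted p = 1.7e-06) and SCGN, a calcium sensor of secretory cells, fell by 7.80 ± 0.70 (adjusted p = 5.33e-05). FHL2 fell by 7.35 ± 0.32 (adjusted p = 5.67e-07). The matrix gene EFEMP1 was at least 101-fold lower (adjusted p = 3.76e-05) and MARCKS at least 47-fold lower (adjusted p = 1.07e-06). CD109, a co-receptor of TGF-beta, was at least 31.1-fold lower (adjusted p = 2.89e-05), and these 3 were not well above background with N119A.

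In the comparison of N119A with wild-type CXCR4 755 genes rose and 1310 fell, or 2777 and 3068 when the arrays that stood apart were left out. Of 28 cholesterol genes 10 fell and none rose, 15 over the list alone (median -1.02, adjusted p = 4.92e-08; adjusted p = 0.692 with an estimated correlation). STARD4 was at least 21.8-fold lower (adjusted p = 2.12e-07) and INSIG1 fell by 2.58 ± 0.38 (adjusted p = 0.00152). Among 33 hypoxia genes 7 fell and 2 rose, in the list alone too (median -0.59, adjusted p = 7.48e-05; adjusted p = 0.692 with an estimated correlation). The pyruvate dehydrogenase kinase gene PDK3 was at least 17.4-fold lower (adjusted p = 4.27e-05), and the hypoxia median was -0.23 without the arrays that stood apart. Of 32 interferon-stimulated genes 11 fell and 1 rose, 15 and 1 over the list alone (median -1.15, adjusted p = 2.49e-06; adjusted p = 0.692 with an estimated correlation). IFIH1 fell by 5.41 ± 0.67 (adjusted p = 0.00049) but the antiviral RSAD2 was at least 8.4-fold higher (adjusted p = 0.00192), and the interferon median was -0.61 without those arrays. Of 21 NF-kB targets 4 fell and none rose, 5 over the list alone (median -1.15, adjusted p = 0.000442; adjusted p = 0.692 with an estimated correlation). CCL2 fell by 4.57 ± 0.57 (adjusted p = 0.00049), and the NF-kB median was -0.66 without those arrays.

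Erythroid genes differed in direction between N119A and wild-type CXCR4. In this list 7 of 41 rose and 2 fell, 9 and 2 over the list alone (median 0.53, adjusted p = 0.0323; adjusted p = 0.779 with an estimated correlation). Without the arrays that stood apart 11 rose and 11 fell (adjusted p = 0.881). CA1 (3.71 ± 0.52, adjusted p = 0.00113) and the glycophorin gene GYPB (3.27 ± 0.52, adjusted p = 0.00258) rose, while CA2 fell by 3.51 ± 0.35 (adjusted p = 0.000115). BCL2L11 rose by 2.67 ± 0.28 (adjusted p = 0.000169), and KIT fell by 4.62 ± 0.60 (adjusted p = 0.000689), 1 of 3 lower and 1 higher among 15 stem and progenitor genes. The death receptor FAS was at least 4.33-fold lower (adjusted p = 0.00104), and the integrin gene ITGA2B fell by 2.19 ± 0.28 (adjusted p = 0.00057). CCNE2 alone of 36 DNA replication genes rose, also over the list alone (median 0.69, adjusted p = 0.00368; adjusted p = 0.779 with an estimated correlation). CDC20 alone of 34 mitosis genes rose, none over the list alone (median 0.63, adjusted p = 0.00186; adjusted p = 0.779 with an estimated correlation). Those 2 list calls were lost without the arrays that stood apart (adjusted p = 0.876 and 0.124). Of 16 fibroblast and epithelial genes 4 fell, 5 over the list alone (median -0.64, adjusted p = 0.0375; adjusted p = 0.779 with an estimated correlation, and 0.448 without those arrays). Within the slide shared by all wild-type arrays and 2 N119A arrays 678 genes passed in place of 2065.

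With N119S against wild-type CXCR4, MS4A4A rose by 8.03 ± 0.37 (adjusted p = 1.49e-06) and RUNX1T1 by 5.93 ± 0.41 (adjusted p = 2.43e-05). EYA2 was at least 127-fold higher (adjusted p = 1.5e-06), ZIC1 at least 18.9-fold higher (adjusted p = 1.7e-05) and MGAT4A at least 17.7-fold higher (adjusted p = 1.04e-05), not well above background with wild-type CXCR4. The cancer-testis antigen MAGEC1 fell by 6.64 ± 0.31 (adjusted p = 1.5e-06) and SCGN fell by 7.35 ± 0.70 (adjusted p = 0.000146). CYB5A was at least 131-fold lower (adjusted p = 0.000121) and CTDSPL, a phosphatase that acts on RB1, at least 32.5-fold lower (adjusted p = 1.07e-05). ENAH, which extends actin filaments, was at least 28.1-fold lower (adjusted p = 4.87e-05), and the 3 genes were not well above background with N119S. SQOR, a mitochondrial sulfide enzyme, fell by 6.68 ± 0.63 (adjusted p = 0.000135). With slide as a term the SQOR difference was -6.65 and did not pass (adjusted p = 0.0521). CREB5 fell by 6.85 ± 0.86 (adjusted p = 0.000836, and 0.154 with slide as a term).

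Here 1193 genes rose and 1164 fell, N119S against wild-type CXCR4. The balance turned with the scaling, to 558 higher and 694 lower with normexp background and 1169 and 1323 with quantile normalization. It was 1037 and 1123 with the percentile of detected probes. Without the arrays that stood apart the excess of higher genes grew instead, to 4388 and 3400. Of 33 hypoxia genes 14 fell and none rose, 23 over the list alone (median -1.27, adjusted p = 1.5e-14; adjusted p = 0.635 with an estimated correlation). PDK3 (-4.79 ± 0.42, adjusted p = 9.22e-05), EGLN1 (-2.39 ± 0.27, adjusted p = 0.000426) and ALDOC (-2.63 ± 0.30, adjusted p = 0.000449) fell, and CA9 was at least 29.5-fold lower (adjusted p = 0.000137). A total of 27 hypoxia genes fell without the arrays that stood apart. Of 28 cholesterol genes 10 fell and none rose, 11 and 1 over the list alone (median -0.88, adjusted p = 4.07e-06; adjusted p = 0.987 with an estimated correlation). STARD4 fell by 3.10 ± 0.24 (adjusted p = 4.38e-05) and INSIG1 fell by 2.39 ± 0.38 (adjusted p = 0.0037). Of 32 interferon-stimulated genes 8 fell and 1 rose, 12 and 1 over the list alone (median -1.23, adjusted p = 1.57e-06; adjusted p = 0.987 with an estimated correlation). The antiviral BST2 fell by 1.84 ± 0.33 (adjusted p = 0.0073), and the interferon median was -0.67 without those arrays. Of 26 histone genes 2 fell, 1 over the list alone (median -0.21, adjusted p = 0.0394; adjusted p = 0.987 with an estimated correlation, and 0.107 with slide as a term). BCL2L11 rose by 2.19 ± 0.28 (adjusted p = 0.001), RGS18 was at least 18.5-fold higher (adjusted p = 0.000374) and FAS at least 4.12-fold lower (adjusted p = 0.00208). With slide as a term 110 genes passed in place of 2357, STARD4, CA9, PDK3 and FAS among them.

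Genes that both substitutions moved alike against control and against wild-type CXCR4 numbered 180 higher and 356 lower. EYA2, MS4A4A, RUNX1T1 and the matrix gene FRAS1 were among the higher, and CYB5A, CTDSPL and MAGEC1 among the lower. Of these, 168 of the higher and 353 of the lower genes did not pass between wild-type CXCR4 and control. In that comparison 140 of all 22429 names passed, so most genes of any set would not pass. For the mean of both mutants against wild-type CXCR4, EYA2 was at least 133-fold higher (adjusted p = 4.1e-07), not well above background with wild-type CXCR4. The mean differences were 8.25 ± 0.32 for MS4A4A (adjusted p = 3.71e-07), -6.71 ± 0.27 for MAGEC1 (adjusted p = 4.1e-07) and -6.83 ± 0.54 for SQOR (adjusted p = 2.51e-05). In that mean 12 of 28 cholesterol genes fell, 16 over the list alone (median -0.97, adjusted p = 6.93e-08; adjusted p = 0.892 with an estimated correlation). The 33 hypoxia genes had 12 lower and none higher, 19 and 1 over the list alone (median -0.95, adjusted p = 4.88e-10; adjusted p = 0.892 with an estimated correlation). The 32 interferon-stimulated genes had 12 lower and 1 higher, 13 and 1 over the list alone (median -1.3, adjusted p = 1.89e-07; adjusted p = 0.892 with an estimated correlation). Of 21 NF-kB targets 3 fell, 5 over the list alone (median -0.93, adjusted p = 0.00305; adjusted p = 0.935 with an estimated correlation). With the arrays that stood apart left out, the medians were -1.43 for the cholesterol, -0.67 for the hypoxia, -0.7 for the interferon and -0.62 for the NF-kB list. In this mean 1158 genes were higher and 1551 lower, or 3900 and 3463 when the arrays that stood apart were left out, and 440 of the 2709 kept their calls with slide as a term.

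Across all genes the N119A and N119S differences against control had r = 0.68 and a covariance of 0.637. Groups simulated without effect against a shared simulated control group gave r = 0.67 and a covariance of 0.138. The simulation drew each gene by itself with the spread of each group, so it holds no slide effect and no correlation between genes. The mutants shared 361 higher genes and 549 lower genes against control, where independent calls would give 34.7 and 51.1 and the simulation gave 0.7 and 0.7. Against wild-type CXCR4 r was 0.71 and the covariance 0.718 (simulated 0.8 and 0.274), with 358 higher and 665 lower genes in common (independent 40.2 and 68, simulated 17.7 and 16.6). Between pairs of comparisons with no array in common, N119A against control and N119S against wild-type CXCR4 had r = 0.54. They had 254 higher and 482 lower genes in common (independent 37.5 and 58.5), EYA2, MS4A4A and CYB5A among them, and 35 opposite calls. The other such pair, N119S against control and N119A against wild-type CXCR4, had r = 0.49. It had 257 higher and 454 lower genes in common (independent 37.2 and 59.3) and 59 opposite calls. Slide 2 held mutant arrays only, so a slide effect can enter both sides of each pair.

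N119S was compared with N119A directly to ask whether the substitutions act alike. EFEMP1 was at least 226-fold higher with N119S (adjusted p = 3.84e-05) and CHST3, a sulfotransferase of chondroitin, at least 55-fold higher (adjusted p = 3.1e-06). CD109 was at least 23-fold higher (adjusted p = 0.000101) and MARCKS at least 13.3-fold higher (adjusted p = 1.97e-05), and these 4 genes were not well above background with N119A. SPARC rose by 6.56 ± 0.45 (adjusted p = 2.8e-05) and the cytokine receptor LIFR by 5.95 ± 0.48 (adjusted p = 7.12e-05). GNG11, a G-protein gamma subunit, fell by 5.78 ± 0.28 (adjusted p = 2.38e-06) and PAGE1 fell by 7.25 ± 0.52 (adjusted p = 3.84e-05). FSTL5, a secreted follistatin relative, was at least 94.3-fold lower (adjusted p = 0.000119), not well above background with N119S. The scavenger receptor CD36 was at least 36.7-fold lower (adjusted p = 0.00554; with slide as a term 0.148).

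In this direct test 470 genes were higher with N119S than with N119A and 223 lower. The excess of higher genes shrank to 212 and 176 with probes above background on all arrays. Without the arrays that stood apart 2164 genes were higher and 2087 lower. Those arrays belong to neither of these groups, so the log2 differences stayed the same and only the spread pooled over all groups changed. Of 15 stem and progenitor genes 2 rose, ABCG2 (4.64 ± 0.42, adjusted p = 0.00014) and KIT (4.15 ± 0.60, adjusted p = 0.00333), and the list did not pass (adjusted p = 0.0602). Among 27 oxidative stress genes 3 rose and 4 fell, the metal-binding genes MT2A (-3.34 ± 0.36, adjusted p = 0.000444) and MT1X (-3.94 ± 0.48, adjusted p = 0.00106) among the lower. ITGB3, an integrin of platelets, was at least 4.69-fold higher (adjusted p = 0.00093) and ITGA2B rose by 1.51 ± 0.28 (adjusted p = 0.0147). These were the 2 of 21 megakaryocyte genes that passed, with 4 higher and 1 lower over the list alone (median 0.48, adjusted p = 0.0249; adjusted p = 0.388 with an estimated correlation, and 0.161 with slide as a term). CA1 fell by 4.02 ± 0.52 (adjusted p = 0.00156), alone among 41 erythroid genes, with 1 higher and 1 lower over the list alone (median -0.35, adjusted p = 0.0145; adjusted p = 0.825 with an estimated correlation, and 0.161 with slide as a term). STARD4 was at least 2.55-fold higher (adjusted p = 4.14e-05). CCL2 alone of 21 NF-kB targets rose, also over the list alone, by 2.63 (median 0.58, adjusted p = 0.0461; adjusted p = 0.825 with an estimated correlation). CD3D alone of 15 lymphocyte genes rose, also over the list alone, by 3.07 (median 0.64, adjusted p = 0.0461; adjusted p = 0.59 with an estimated correlation, and 0.46 with slide as a term).

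Histone, growth and stress lists ranked lower with N119S than with N119A, though few of their members passed. H1-4 alone of 26 histone genes fell (-1.20 ± 0.20, adjusted p = 0.008), 2 over the list alone (median -0.53, adjusted p = 4.29e-06; adjusted p = 0.388 with an estimated correlation). Of 33 hypoxia genes 2 fell, or 3 lower and 1 higher over the list alone (median -0.53, adjusted p = 3.35e-06; adjusted p = 0.579 with an estimated correlation). They were the oxygen sensor EGLN3 (-1.47 ± 0.26, adjusted p = 0.0128) and DDIT4, an inhibitor of mTOR (-2.67 ± 0.57, adjusted p = 0.0315). PHGDH, which opens serine synthesis, fell by 3.15 ± 0.67 (adjusted p = 0.0309). It was 1 of 2 lower among 28 unfolded protein and ATF4 genes, with 5 lower and 1 higher over the list alone (median -0.64, adjusted p = 0.000182; adjusted p = 0.726 with an estimated correlation). The origin recognition gene ORC1 fell by 1.37 ± 0.28 (adjusted p = 0.0253). It was alone among 36 DNA replication genes, also over the list alone (median -0.39, adjusted p = 0.00055; adjusted p = 0.825 with an estimated correlation, and 0.0734 with slide as a term). None of 34 mitosis genes passed (median -0.43, adjusted p = 0.00055; adjusted p = 0.825 with an estimated correlation), nor any of 40 respiratory chain subunits (median -0.12, adjusted p = 0.0451; adjusted p = 0.909 with an estimated correlation, and 0.739 with slide as a term).

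Opposite calls against wild-type CXCR4 were found at 24 genes, all of which also passed between N119S and N119A. GNG11 was 2.70 with N119A and -3.09 with N119S, LIFR -3.52 and 2.42, and the homing receptor CCR7 -2.48 and 1.82. An opposite call against wild-type CXCR4 need not be opposite against control. Normalized GNG11 values on the N119S arrays (-3, -2.85 and -2.8) lay near those in control (-2.64, -2.14 and -2.87). The wild-type CXCR4 arrays were higher (0.28, 0.55 and -0.21). CHST3 and ITGB3, lower with N119A and higher with N119S, and FSTL5, the other way, were not well above background where they were lower. Against control 29 genes had opposite calls. All N119S arrays and a single N119A array lay on one slide. Over all arrays 169 of the 693 kept their calls with slide as a term, among them EFEMP1, CHST3, SPARC, GNG11, PAGE1 and FSTL5.

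**Figure D3:**
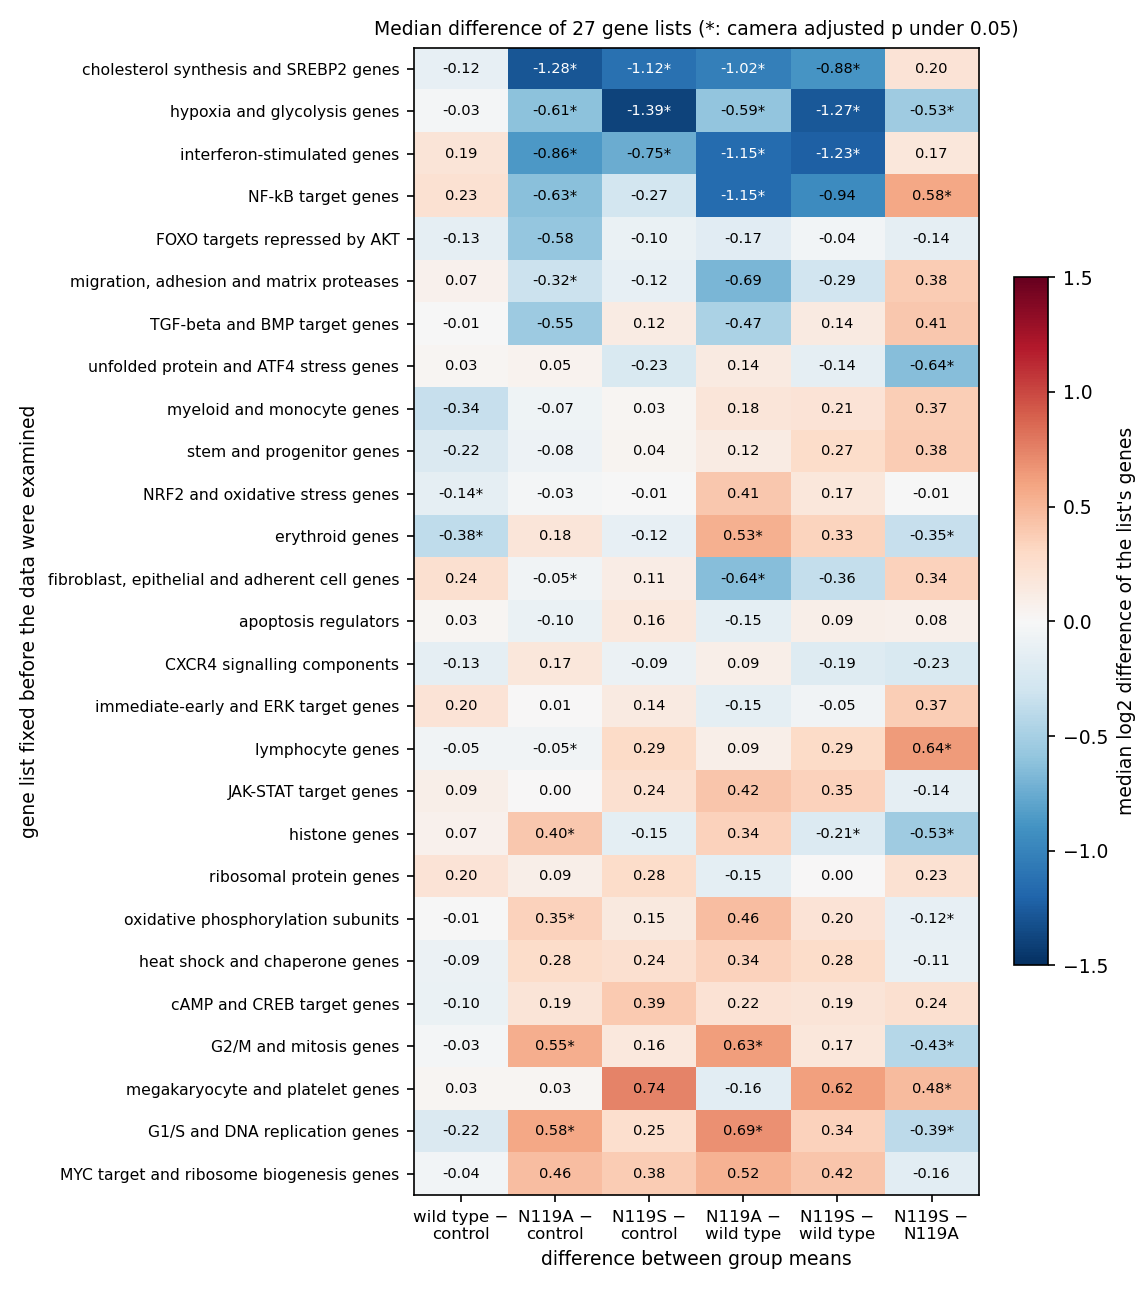
Median log2 difference of 27 gene lists in 6 comparisons. Cholesterol, hypoxia and interferon lists were lower with both mutants by camera at the preset correlation, and none of these calls stayed with an estimated correlation.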

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

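All tests of this part were chosen after the results were seen, except the splits of the arrays and the slide test of N119S against N119A, which were chosen before. The effects of N119S and N119A differed at 693 genes, EFEMP1, SPARC and GNG11 among them, and were opposite at 24 genes against wild-type CXCR4 and at 29 genes against control. These results stood out as differences between the effects of groups that the labels describe by the same property.

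Control replicate 1 and wild-type CXCR4 replicate 2 deviated alike from their groups (r = 0.52). Low signal was set aside as the source for control replicate 1, since 26.2% of its brightest genes (top 25%) lay over 1 log2 from its group, against at most 4.6% on the 10 arrays outside this pair. For wild-type CXCR4 replicate 2 that share was 38.3% at the lowest 75th-percentile signal of all arrays (96.8), so low signal stays open there. A swap of these arrays was tested too, and control replicate 1 lay at 0.3 of the way to wild-type CXCR4, short of the place a swap would give. All 16 lists that moved by 0.5 log2 or more on both arrays moved the same way, with erythroid, replication and cholesterol genes lower and interferon and NF-kB genes higher. This describes how alike the arrays are and does not separate the possible sources, so the source was left open.

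The 536 genes that both mutants shared against control and wild-type CXCR4, EYA2 and CYB5A among them, were set against 3 sources. For the N119A differences slide was set aside as the whole source: of the 2120 genes past the threshold for N119S against control, 316 passed the same way and 28 the opposite way for N119A replicates 1 and 2 against wild-type CXCR4 within slide 1, with no array in common. At 60 of the 536 genes both N119S calls stayed with slide as a term, so a slide effect of the size seen in N119A did not account for them. That size was read from a single N119A array on slide 2, at genes picked for N119A calls too, so slide is not excluded there. For the other 476 slide and substitution cannot be told apart either, since slide is estimated through that array. Over all 536 the median N119S difference from wild-type CXCR4 went from 2.16 (median SE 0.33) to 2.12 (median SE 0.6) with slide as a term, but genes picked for N119A calls have like N119A arrays by choice. At 1358 genes called for N119S without the N119A arrays, N119A replicate 3 differed from replicates 1 and 2 by a median share of 0.21 of the difference between N119S and wild-type CXCR4, with quartiles of -0.01 and 0.79. The shared calls did not need the arrays that stood apart, since 534 kept all calls without them. More genes passed in every comparison there, so few losses were likely beforehand. Divergence between separately kept cell lines cannot be told apart from an effect of the substitutions: wild-type CXCR4 against control, which differ also in receptor, transfection and induction, had 35 genes with at least 3 log2, against 415 for N119A and 313 for N119S. Part of the overlap may come from shared control arrays, where simulated covariance was 0.138 beside an observed 0.637.

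The 693 genes between N119S and N119A lie largely across slides, and N119A replicate 3, the array on the N119S slide, was at a median position of 0.51 between the other N119A arrays and the N119S arrays at 1249 genes called without it. An effect of slide and an effect of the substitution cannot be told apart from this value, which had quartiles of 0.09 and 1.06.

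Splits of the same arrays into other groups could not give a share under 0.05 for any comparison of 3 with 3 arrays, since only 10 exist. The real split had the highest count in each (1 of 10), and the highest other split gave 2 genes for wild-type CXCR4 against control, 1 for N119A against wild-type CXCR4 and for N119S against N119A, and 0 for the other 3. For the mean of both mutants against wild-type CXCR4 1 of 84 splits had as many genes, the real one, and the highest other gave 1303 with the N119A arrays as the set of 3. Most of these 84 splits put arrays of different groups together, which widens the spread and removes calls in advance. The other splits of 3 with 3 arrays mix groups as well, so none of these shares measures chance.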

How the results depend on the processing

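Leaving out the arrays that stood apart and moving the series table to the control baseline were chosen after seeing the result; all other alternatives were chosen before. The order below is wild-type CXCR4, N119A and N119S against control, N119A and N119S against wild-type CXCR4, N119S against N119A, and the mean of both mutants against wild-type CXCR4. Every count stayed within 1.5 times under quantile normalization, the percentile of detected probes, joined or single probes, trended robust moderation, slide as a random block, the series table on the control baseline and a limit of 1 log2. With single probes the counts were of probes, from the 33639 kept, not of the 22429 names, so these are not like for like. The random block had an estimated correlation of -0.04, so it made no allowance for slide and its counts do not bear on a slide effect. Normexp background gave 76, 1180, 1127, 1369, 1252, 377 and 1599 genes, array weights 3463, 6416, 12147, 5512, 11581, 6555 and 9168, and the fit without the arrays that stood apart 1068, 5215, 6290, 5845, 7788, 4251 and 7363. Other counts moved in part. Probes above background on all arrays gave 65 for wild-type CXCR4 against control and 388 for N119S against N119A. No filter gave 1345 for N119S against control and 1518 for N119S against wild-type CXCR4. Only the groups compared gave 2 for wild-type CXCR4 against control, 4096 for N119S against control, 841 for N119A against wild-type CXCR4 and 2844 for N119S against N119A. Slide as a term gave 1.2e+02 for N119S against control (111 of them among the 2120), 1358 for N119A and 110 for N119S against wild-type CXCR4, 173 for N119S against N119A and 449 for the mean. Within a single slide the counts were 588 for N119A against control, 678 for N119A against wild-type CXCR4 and 1368 for N119S against N119A, with fewer arrays and in the last case a single N119A array, assumed to vary like the other groups. The side of the slide (1 of 2) as a term gave 17 for wild-type CXCR4 and 928 for N119A against control, 567 for N119S against wild-type CXCR4, 268 for N119S against N119A and 1565 for the mean. The series table as deposited gave 4735, 5895 and 6766 for N119A, N119S and the mean against wild-type CXCR4, where its 2 baselines enter the difference. Leaving out each array gave 27 to 421, 1222 to 3680, 689 to 4695, 1358 to 2798, 781 to 4077, 319 to 1577 and 1644 to 3657, the highest always without wild-type CXCR4 replicate 2. For comparisons that do not use wild-type CXCR4 replicate 2, leaving it out cannot change the log2 differences, so there only the pooled spread changed. Apart from this, the series table and the smaller sets of arrays, the cause was not tested.

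A replicate block gave 43 for wild-type CXCR4 against control, 1271 for N119S against control and 1468 for N119S against wild-type CXCR4, and no other count left 1.5 times. Arrays of the same number in different groups had residual r from -0.45 to 0.39 (median -0.1), over 0.1 in 3 of 18 pairs against 10 of 36 of different number. Residuals balance within a group, so control replicate 1 and wild-type CXCR4 replicate 2 shape all pairs of control and wild-type arrays. Whether the numbers mark pairs was therefore left open.

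For 516 named gene results 14390 values were computed: 12618 counted as kept, 1757 kept direction and lost the call, 13 gained a call and 2 reversed. A called result counted as kept with the same direction and call. A result not called in the main fit counted as kept if it again did not pass, even where its direction changed. Only called results could count as reversed. All 13 were CXCR4. Calls were lost most with slide as a term (237), and 3 were lost without the arrays that stood apart. AKR1C3 reversed for N119S against wild-type CXCR4 with slide as a term (-0.52, adjusted p = 0.959), and ERG for the mean against wild-type CXCR4 in the series table on the control baseline (-0.05, adjusted p = 0.976); the cause was not tested. Of 42 list calls none reversed, 37 stayed with normexp background, 33 with quantile normalization, 35 with slide as a term, 42 with the replicate block, 30 without the arrays that stood apart, 30 to 41 without each array, 9 with fry and 0 with an estimated correlation. The median of all genes against control moved from 0.19 to 0.08 for N119S with quantile normalization and from 0.1 to -0.02 for N119A with the percentile of detected probes. The 75th-percentile signal of 96.8 on wild-type CXCR4 replicate 2 limits dim genes there, where 50.5% of probes were well above background.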

Other observations

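The families of this part were chosen after the values were seen. Of 12 metallothioneins, which bind zinc and copper, 8 rose with N119A against control, by 3.70 to 4.29. Among them were MT1E at 4.29, MT1H at 4.24 and MT2A at 4.10, and the median of all 12 was 4.04. Normexp background left 7 and the other scalings 8, and near-identical members can share probes. With N119S against control none passed (median 0.37), and with wild-type CXCR4 none did (median 0.16). Between N119S and N119A 8 fell (median of all 12 -3.4), which tests the difference, and 4 did with slide as a term. Without the arrays that stood apart 3 rose with N119S against control and 7 against wild-type CXCR4.

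Of 6 genes of the MS4A family, a cluster of membrane proteins of blood cells, 4 rose with N119A against control, MS4A4A by 8.41, MS4A3 by 8.36, and MS4A6A and MS4A2 from levels not well above background. The same 4 rose with N119S against control, MS4A4A by 7.96 and MS4A3 by 6.69. With wild-type CXCR4 against control 2 of the 6 rose, MS4A3 by 3.89 and MS4A2, not well above background in either group. In that comparison 1 rose with normexp background and 1 with quantile normalization. None fell against control under any scaling, with 2 higher for N119A and 3 for N119S under normexp background. Cancer-testis antigens moved both ways: of 43, 7 rose and 13 fell with N119A against control, PAGE1 by 5.79 and MAGEC2 by -5.37, and 6 rose and 10 fell with N119S, PAGE2 by 3.59 and MAGEC1 by -5.95. Normexp background left 8 higher and 9 lower for N119A against control and 7 and 7 for N119S, and slide as a term left 6 and 11 for N119A and 3 and 1 for N119S. None of 10 globin genes passed in any comparison over all arrays in the scaling used, and with normexp background 1 was higher for N119A and for the mean of both mutants against wild-type CXCR4. Without the arrays that stood apart 5 fell with N119A against control and 2 rose and 5 fell with N119S against control.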
